A study of Homo sapiens with 7 samples.

How the data were processed

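The series holds 7 samples of cultured monocytes from human cord blood, 4 RNA and 3 ATAC libraries, grouped by assay from their titles. Nothing was tested between assays as groups, and replicate numbers were not taken to pair an RNA library with an ATAC library.

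The RNA values are TPM that the authors made with HOMER, per the file headers, by counting reads in exons with 1 transcript kept per gene. STAR 2.7.9a, HOMER, DESeq2 and FastQC and the build hg38 are listed, without roles, per the submitters' processing notes. Libraries came from a stranded mRNA kit, per the labels' protocols. Because the deposited TPM columns sum to at most 390950, well below the total that TPM have over a whole table, values are compared only within this table; why the sums are lower was not tested. No mitochondrially encoded gene is listed. TPM do not carry depth directly, but TPM times transcript length moved in whole steps. The step gave the estimated reads, with 100% of testable genes whole within 0.1 read (1568 to 1675 genes per library). These reads were used for depth, for a chi-square comparison of libraries over genes with 20 or more reads in the pair, and for thinning, not for a count test.

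The ATAC files are peak lists called by the authors on each library alone with HOMER findPeaks without an input control, per the file headers, in factor mode with peaks of 200 bp, a minimum distance of 200 bp, a false discovery rate of 0.001 and 4-fold over the surrounding 10000 bp. The signal in each peak is a tag count the authors scaled to a total of 10000000 tags, and the score is the findPeaks score the authors deposited, from tags counted at most once per position. The lists also give, per the file headers, a fold (ratio) over the surroundings, a clonal fold ratio, a p-value against the surroundings and a focus ratio, which is a fraction of tags near the centre. The aligner, the shift for the transposase and any mitochondrial or duplicate filter of the ATAC libraries are not given in the sources used here. With 4850943 to 6255666 tags per library and a threshold of 8 tags, a missing peak does not show closed chromatin. A fragment size selection before single-end sequencing, per the labels' protocols, favours short fragments.

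From these files the following was computed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. A gene was called expressed at 1 TPM or more in every RNA library. Levels were analysed as log2(TPM + 1), so differences of low genes are understated. Lists of marker and pathway genes, 29 lists of 386 entries, were fixed before the data were examined, and list medians were compared inside each library with an exact two-sided sign-flip permutation test over 4 libraries and Benjamini-Hochberg adjustment over 28 lists. The smallest p is 0.125.

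Peaks were merged where they overlapped by 1 bp or more, and a region was shared where all 3 libraries had a peak. Random overlap came from 100 placements of the peaks on their chromosomes. Start sites, transcript ends and strands came from the RNA files. For the join of assays, 26270 genes with 1 copy on the main chromosomes were used and 1765 others were left out. Expression of genes with and without a shared promoter peak was compared by a two-sided permutation test of medians with 100000 resamples, and lists by a two-sided Fisher's exact test against the other expressed genes, adjusted over the 26 lists with an expressed member. The depth estimate, the merging of peaks, the list test and the permutation test were tested on simulated data, where the planted steps and regions and most planted lists were recovered. Planted lists all had the size of the monocyte list, larger than most tested lists, so their recovery does not carry over to smaller lists. The sign-flip test was only run on a made-up set of differences of a single sign.

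Genes were named by a rule fixed with the lists: the MEF2 genes, the members of each list with the highest mean TPM (up to 4, and up to 6 for the monocyte, microglia and transcription factor lists), commonly used markers below the threshold, and the 15 genes with the highest mean TPM outside ribosomal protein and mitochondrially encoded genes. CD14, P2RY12, TMEM119, SALL1, C1QA, C1QC, CD34, TREM2, APOE, VCAN, ABCA7, ADAM10, PLCG2, TMEM106B, MKI67, NR4A1, CXCR1, CXCR2, MMP25, IER2, PCBD2 and FOSB were named after their values were seen. Sex-linked marker genes and genes with common deletions or donor-specific haplotypes were left out of all tables of single genes, and some other list members are not reported singly. The planned search for transcription factor motifs was not run, because it needs a genome sequence, which is not used here. Alternatives covered left-out libraries, scaling without 87 ribosomal protein genes, pseudocounts, thresholds, overlaps, peak numbers and promoter widths.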

Results

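Monocytes from human umbilical cord blood, kept in vitro, were profiled by RNA sequencing in 4 libraries and by ATAC-seq, which maps open chromatin with a transposase, in 3 libraries. The design text names the purpose as a comparison with microglia from stem cell lines edited at MEF2C, a transcription factor gene. The microglia libraries are not analysed here, so the levels below describe 1 condition and marker genes were compared inside each library. The labels do not say whether the libraries came from separate donors or cultures, so the spread between them may be technical. The p-values over libraries concern these libraries only. Where all 4 differences share a sign, the sign-flip p is the same whatever their spread.

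The RNA files listed 28035 genes in TPM, a count scaled by transcript length and library total. The listed values summed to 390950, 385786, 387810 and 387043 TPM in libraries 1 to 4. The steps between low TPM values gave estimated totals of 9562644, 19065596, 15246850 and 14941129 reads over the listed genes. In all, 12064 genes reached 1 TPM in every RNA library, with 13115, 13357, 13173 and 13090 in libraries 1 to 4 taken singly. At a threshold of 5 TPM the number in every library was 7795.

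The RNA libraries did not resemble one another equally. Across 14366 genes, Pearson's r of log2(TPM + 1) was 0.984 between libraries 2 and 3 and 0.974 between libraries 1 and 4, and lay between 0.950 and 0.955 for the other 4 pairs. Genes are not independent replicates. As a check for a library deposited more than once, the chi-square per degree of freedom of the estimated reads was 5.90 for libraries 2 and 3, 6.43 for libraries 1 and 4 and at least 34.5 for the rest, measured against counting error only. All 4 libraries were kept. For some of the genes and lists that differed along this line values are given per library, and for the others as mean ± SD. An SD can therefore reflect the gap between these pairs of libraries and not an even spread. Examples are the list medians of granulocyte precursor genes (6.02, 5.54, 5.41 and 5.94 in libraries 1 to 4) and of major histocompatibility class II genes (7.14, 6.80, 6.78 and 7.19).

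The list of classical monocyte marker genes had the highest median of the 29 gene lists. S100A9, a calcium-binding alarmin, reached 9837 ± 341 TPM (SD, n = 4), LYZ, which encodes lysozyme, 4859 ± 306 TPM, and S100A8, the partner of S100A9, 3949 ± 373 TPM. CSF3R, the receptor for granulocyte colony-stimulating factor, stood at 1148 ± 235 TPM, MNDA at 735.0 ± 109 TPM and CTSS, a lysosomal protease, at 717 ± 44.2 TPM. CD14, the lipopolysaccharide co-receptor that names this cell type, had 451, 611, 619 and 425 TPM in libraries 1 to 4. All 15 genes of the monocyte list were expressed in every library, and the list median was 9.16 ± 0.12 on the log2(TPM + 1) scale (SD, n = 4). S100A9, S100A8, CSF3R and MNDA are also expressed by neutrophils, and a list of 7 mature neutrophil genes, set together after values were seen, had medians of 268, 227, 205 and 317 TPM in libraries 1 to 4. The nonclassical monocyte list had a median of 6.19 ± 0.10, with LST1 at 450.0 ± 39.4 TPM. LST1 is listed with 8 copies in the build, so its reads may be shared between them. Whether listed copies are separate genes or alternative sequences of the build was not tested.

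Homeostatic microglia genes, the markers of the cells the study set beside these monocytes, lay far below the monocyte genes. The list median was 1.84, 3.12, 3.34 and 1.88 in libraries 1 to 4, and the monocyte list exceeded it by 6.62 ± 0.68 on the log2 scale (SD, n = 4), in 4 of 4 libraries. Members that monocytes also use were abundant, among them SELPLG, a selectin ligand, at 182 ± 16.3 TPM, the purinergic receptor gene P2RY13 at 106 ± 20.5 TPM and CSF1R, the receptor for colony-stimulating factor 1, at 103 ± 8.87 TPM. CX3CR1, the fractalkine receptor gene, had 124, 59.5, 66.3 and 132 TPM. P2RY12 had 2.58, 2.04, 2.50 and 2.69 TPM, TMEM119 stayed below 1 TPM in every library, and SALL1, a microglial transcription factor gene, was listed at 0 in all 4. The complement gene C1QA had 1.55, 12.2, 12.6 and 1.72 TPM, so libraries 2 and 3 stood above libraries 1 and 4. The list median moved the same way, but in libraries 2 and 3 it was the value of C1QC, another complement gene (7.70 and 9.14 TPM). In libraries 1 and 4 it was that of P2RY12. This shift of the median does not show that the list as a whole moved, and some members, such as CX3CR1, went the other way.

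The other comparisons with the monocyte list went the same way. The macrophage list (median 1.57 ± 0.19) lay 7.60 ± 0.09 below it, the stem and progenitor list (1.53 ± 0.19) 7.63 ± 0.08 below, and the granulocyte precursor list (5.73 ± 0.30) 3.44 ± 0.41 below (SD, n = 4). Macrophage genes included CHI3L1 at 41.9, 99.6, 89.0 and 43.5 TPM and the scavenger receptor gene CD163 at 40.4 ± 8.02 TPM. Among progenitor genes SOX4 had 14.4 ± 2.67 TPM, GATA2 5.77, 14.4, 14.7 and 5.60 TPM, and CD34 1.84, 4.73, 4.64 and 2.54 TPM. All 12 granulocyte precursor genes were expressed in every library, with the azurophil granule genes ELANE at 95.7 ± 18.5, AZU1 at 76.4 ± 21.3 and MPO at 75.1 ± 5.26 TPM. ELANE and AZU1 are listed with 2 copies each in the build, as are SERPINA1 and B2M named further on, so their reads may be shared. The exact two-sided sign-flip test gave p = 0.12 for each of the 28 lists compared with the monocyte list, adjusted p = 0.12. That is the smallest p this test gives with 4 libraries, so it could not reach 0.05 for any contrast.

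**Figure D1:**
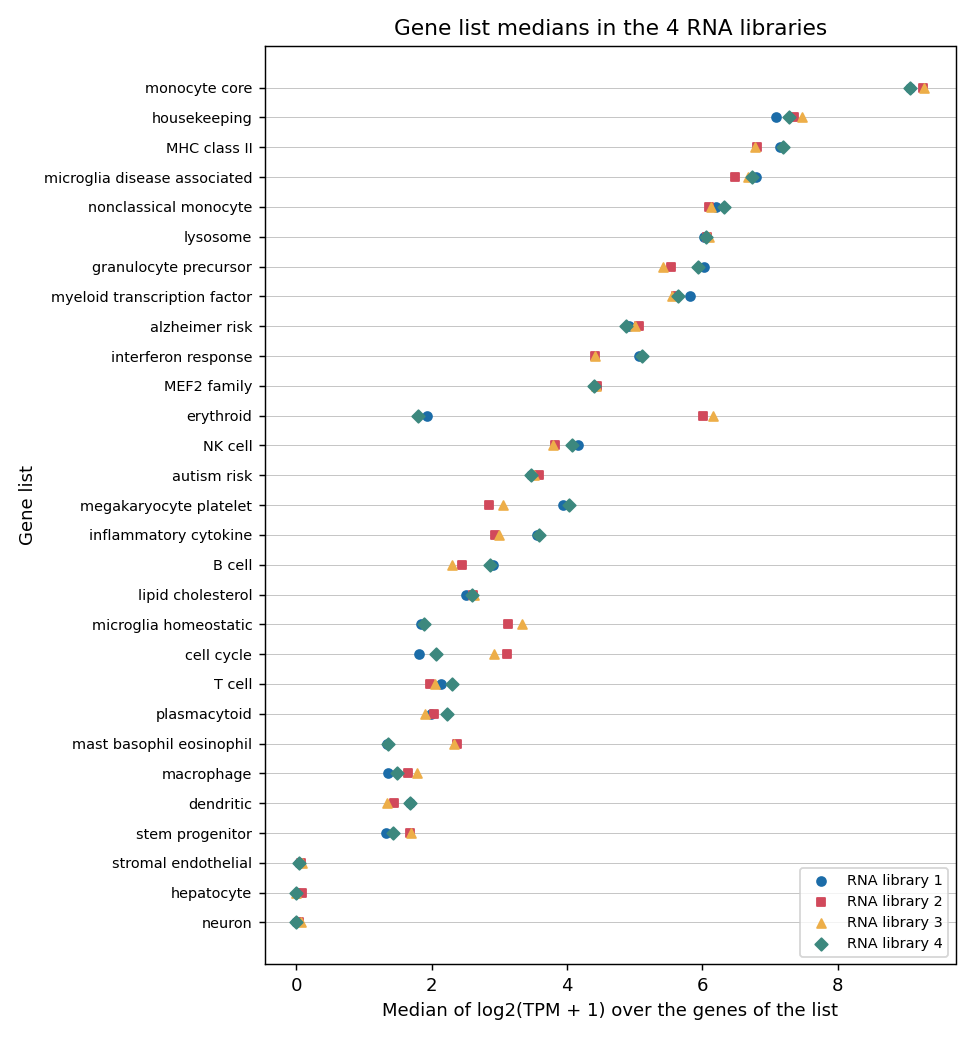
Median of log2(TPM + 1) over the genes of each of 29 lists (horizontal axis), with 1 point for each of the 4 RNA libraries. The monocyte list lies highest, with a mean of 9.16 over libraries, and the erythroid list spreads from 1.79 to 6.15.

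Markers of other blood cells were present at several levels, and some moved between libraries. The erythroid list median was 1.93, 6.01, 6.15 and 1.79 in libraries 1 to 4. HBB, which encodes beta globin, had 22.7, 1512, 1736 and 26.1 TPM, and the fetal globin gene HBG2 9.47, 793, 910 and 18.4 TPM. The erythroid genes together held 0.018, 0.94, 1.05 and 0.021% of the TPM of libraries 1 to 4. Platelet genes went the other way, with a list median of 3.95, 2.85, 3.05 and 4.03 and PF4 at 49.3, 8.69, 10.3 and 46.8 TPM. The B cell list stood at 2.90, 2.44, 2.31 and 2.86, and the mast cell, basophil and eosinophil list at 1.34, 2.37, 2.33 and 1.36, with CLC, a galectin of eosinophils and basophils, at 185, 404, 450.0 and 187 TPM.

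Natural killer genes had a list median of 3.96 ± 0.19, with NKG7 at 138 ± 6.41 TPM and the perforin gene PRF1 at 67.6 ± 3.83 TPM (SD, n = 4). Per library the list median was 4.16, 3.82, 3.79 and 4.08 in libraries 1 to 4. GNLY had 119, 35.7, 32.4 and 102 TPM and GZMB 28.0, 45.4, 51.0 and 24.5 TPM, so these genes moved between libraries in opposite directions. The T cell list stood at 2.11 ± 0.14, with CD3E at 9.18 ± 1.29 TPM, the plasmacytoid list at 2.04 ± 0.14 and the dendritic list at 1.54 ± 0.17, with CD1C at 9.92 ± 1.53 TPM. Genes of tissues outside the blood were near the floor. The medians were 0.06 ± 0.02 for stromal and endothelial genes, 0.03 ± 0.03 for neuronal genes and 0.03 ± 0.04 for hepatocyte genes, of which only SERPINA1, a protease inhibitor that monocytes also make, reached 1 TPM in every library, at 404 ± 29.2 TPM.

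MEF2C was expressed in every RNA library, at 16.1, 17.6, 17.2 and 16.0 TPM (mean 16.7 ± 0.81, SD, n = 4), from an estimated 986, 2145, 1709 and 1523 reads. Its paralogs MEF2A at 28.7 ± 4.58 TPM and MEF2D at 25.9 ± 1.49 TPM were higher, and MEF2B at 11.9 ± 2.82 TPM was lower. On the log2(TPM + 1) scale MEF2C minus MEF2A was -0.73 ± 0.29 and MEF2C minus MEF2D was -0.60 ± 0.08, below 0 in 4 of 4 libraries each (exact two-sided sign-flip test, p = 0.12, the smallest this test gives). The gap to MEF2A was -0.94, -0.45, -0.52 and -1.02 in libraries 1 to 4, and -0.48 over libraries 2 and 3 alone. The MEF2 list median was 4.42 ± 0.02.

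**Figure D2:**
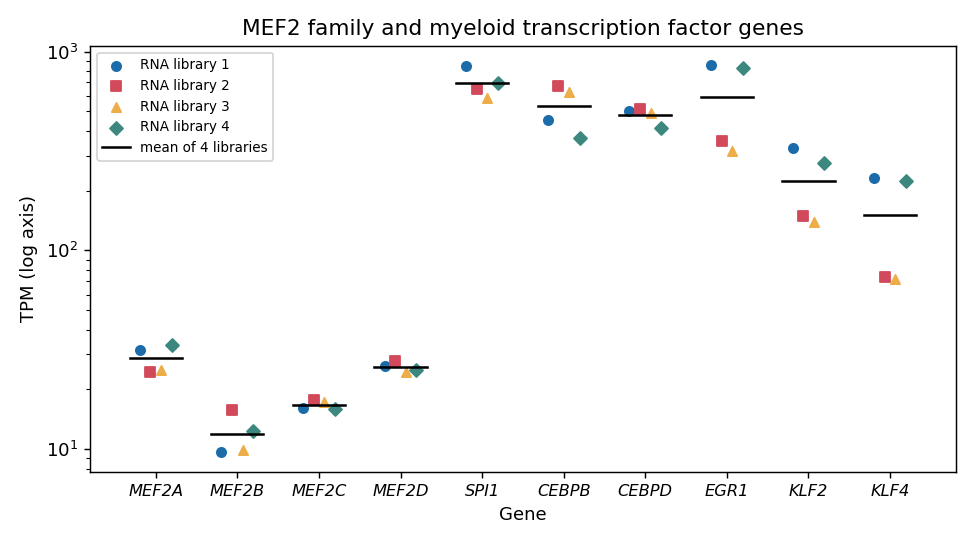
TPM on a log axis for the 4 MEF2 genes and 6 myeloid transcription factor genes, with 1 point per RNA library and a bar at the mean of 4 libraries. MEF2C lies between 16.0 and 17.6 TPM in all libraries, and EGR1, KLF2 and KLF4 are higher in libraries 1 and 4 than in libraries 2 and 3.

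Myeloid transcription factor genes were high, with a list median of 5.66 ± 0.11 and 18 of 19 members expressed in every library. SPI1, which encodes the myeloid master regulator PU.1, had 694 ± 113 TPM, CEBPB 455, 671, 625 and 368 TPM and CEBPD 479 ± 44.6 TPM. EGR1 had 853, 354, 315 and 830.1 TPM, KLF2 327, 149, 139 and 275 TPM, and KLF4 232, 73.3, 72.0 and 222 TPM in libraries 1 to 4.

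Disease-associated microglia genes had a median of 6.67 ± 0.13, carried by genes that myeloid cells share, such as FTH1, which encodes ferritin heavy chain, at 2495 ± 402 TPM, and TYROBP, an adaptor of immune receptors, at 794 ± 66.4 TPM. TREM2 stayed below 1 TPM in every library and APOE had 0.51, 1.70, 2.23 and 0.43 TPM. Genes near Alzheimer's disease risk loci had a median of 4.96 ± 0.09, with 22 of 25 expressed in every library, MS4A6A at 278 ± 21.1 TPM and SORL1 at 129 ± 7.70 TPM. This list shares APOE and TREM2 with the disease-associated list, GRN with the lysosome list and SPI1 with the transcription factor list. Autism risk genes had a median of 3.51 ± 0.05, with 17 of 24 expressed in every library, among them DYRK1A at 24.6 ± 2.18 TPM.

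Antigen presentation and lysosome genes were among the highest lists. The major histocompatibility class II list had a median of 6.98 ± 0.22, with CD74, the invariant chain gene, at 1715 ± 247 TPM, and the lysosome list 6.06 ± 0.03, with PSAP at 1044 ± 96.1 TPM and CD68 at 337 ± 33.0 TPM. Most class II members, though not CD74, are listed with 8 copies each in the build, so their reads may be shared. Interferon response genes stood at 5.06, 4.41, 4.42 and 5.11 in libraries 1 to 4 and inflammatory genes at 3.56, 2.93, 3.00 and 3.58, with IL1B at 149, 92.2, 94.4 and 162 TPM and CXCL8 at 136, 73.2, 76.7 and 166 TPM. Cell cycle genes went the other way, at 1.81, 3.11, 2.93 and 2.06, with the proliferation marker MKI67 at 2.51, 7.62, 7.57 and 2.32 TPM, as did the erythroid list (1.93, 6.01, 6.15 and 1.79) and the progenitor gene GATA2. The lipid and cholesterol list stood at 2.59 ± 0.05, with SREBF2 at 21.2 ± 3.85 TPM, and the housekeeping list at 7.30 ± 0.16, with ACTB at 4916 ± 275 TPM.

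Of the 15 most abundant genes outside ribosomal protein genes, the remaining ones were B2M (3081 ± 236 TPM), the ferritin light chain gene FTL (3686 ± 262), FOS (2652 ± 989), JUNB (2339.6 ± 747) and DUSP1 (1527 ± 345), IFITM2 (1995 ± 407), TMSB4X (1462 ± 121), and the small nucleolar RNA genes SNORD141A (1725 ± 177) and SNORD141B (1695 ± 172). SNORD141A and SNORD141B are listed with 3 copies each and at the same place, chromosome 6, 73518245 to 73518438, so they share reads. The libraries came from an mRNA kit, so these reads may belong to a longer transcript at that place, which was not tested. The values are therefore not read as levels of small nucleolar RNA.

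The ATAC libraries held 5989793, 4850943 and 6255666 tags and 18615, 11480 and 19385 peaks of 200 bp in libraries 1 to 3, with 6.17, 4.60 and 6.57% of tags in peaks. These shares include a few regions with very many tags, given under Other observations, that are not read as open chromatin. Of 25162 merged regions, 9041 overlapped a peak of each library, 5870 of 2 libraries and 10251 of a single one. Peaks placed at random on the same chromosomes gave at most 1 region in all 3 libraries over 100 placements. Of the peaks of library 2, 83.3% overlapped a peak of library 1 and 85.2% one of library 3, while 51.4% of library 1 and 50.6% of library 3 peaks overlapped library 2, which has the fewest tags. Restricted to the 50% of peaks with the highest scores in each library, the shared number was 4884. Across shared regions the Spearman correlation of normalized tags between libraries was 0.738 to 0.798.

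**Figure D3:**
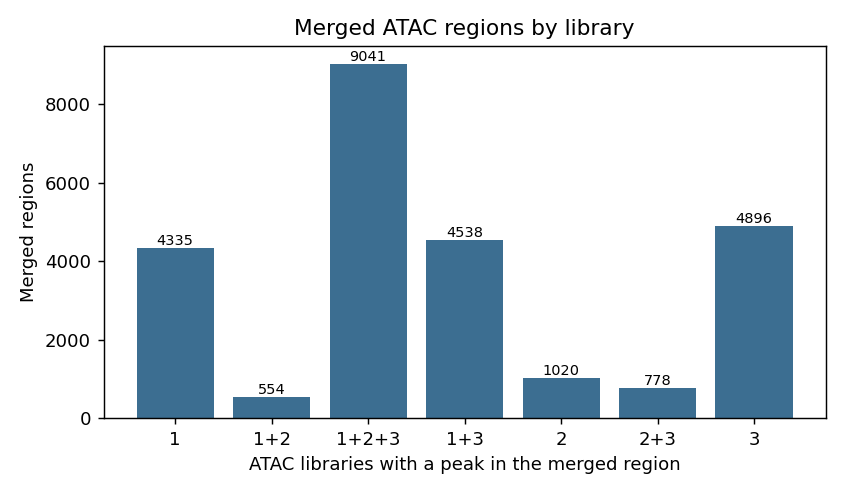
Number of merged ATAC regions (vertical axis) by the libraries with a peak in them (horizontal axis). The 9041 regions with a peak in all 3 libraries form the tallest bar, followed by 4896 in library 3 alone.

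Shared regions lay mostly at promoters. Of the 9041 shared regions, 64.8% overlapped the window from 1000 bp upstream to 100 bp downstream of a listed transcription start site, 17.6% lay elsewhere in a listed transcript and 17.6% outside. The promoter share was 38.9% for regions in 2 libraries and 22.4% for those in 1, and 47.6, 57.7 and 46.1% for all peaks of libraries 1 to 3. The median normalized tag count of peaks was 32.6, 28.9 and 33.6 in shared regions and 15, 18.6 and 15.2 in regions of a single library.

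Genes with a shared promoter peak were more highly expressed. The median of mean log2(TPM + 1) was 3.18 for 6513 genes with such a peak and 0.21 for 19757 genes without, a difference of 2.97 (two-sided permutation test across genes, p = 1e-05, the smallest that 100000 resamples give). The difference was 2.98 to 3.08 in the 12 pairs of 1 ATAC and 1 RNA library. It was 5.22 with a pseudocount of 0.1, and 0.27 among genes at 1 TPM or more in every library (permutation p = 1e-05). The share of genes with a shared promoter peak was 6.53% below 1 TPM (95% Wilson interval 6.13 to 6.96), 51.9% from 10 to 50 TPM (50.5 to 53.4) and 37.0% at 500 TPM or more (26.8 to 48.5), where 73 genes lay. With a peak of any library the share was 75.4% from 10 to 50 TPM and 76.7% at 500 TPM or more. The intervals cover counting error only.

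**Figure D4:**
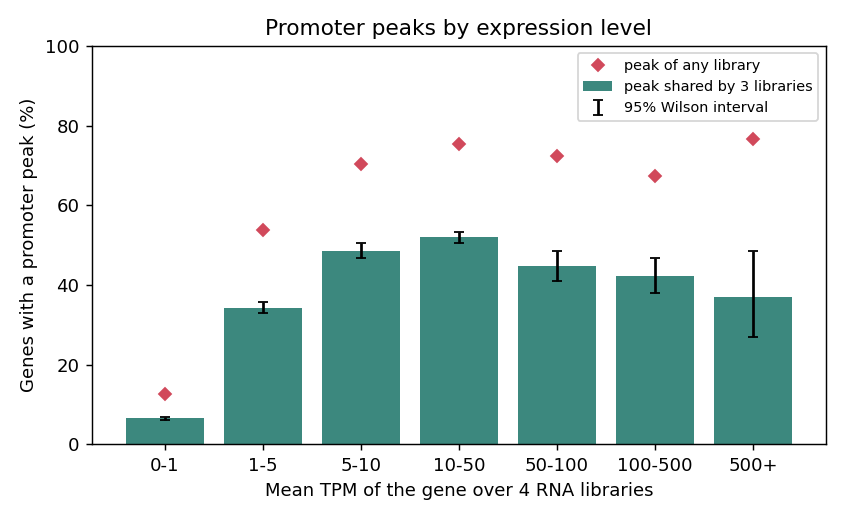
Percentage of genes with a promoter peak (vertical axis) by mean TPM over 4 RNA libraries (horizontal axis). Bars give peaks shared by 3 ATAC libraries with 95% Wilson intervals and diamonds peaks of any library. The bars rise to 51.9% at 10 to 50 TPM and are 37.0% at 500 TPM or more.

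The most abundant monocyte genes mostly lacked a shared promoter peak. Of the 15 monocyte list genes 1 had one, VCAN, against 46.9% of the other 11548 expressed genes (two-sided Fisher's exact test, p = 0.0013, adjusted p = 0.023 over 26 lists). The S100A8 transcript in the files spans 153390032 to 153422583 on chromosome 1 and is 1 of several annotated, so the promoter window does not cover other start sites of that gene. S100A9, LYZ and SPI1 had promoter peaks in libraries 1 and 3 and MNDA in library 3. In all, 9 of 26 lists differed from the other expressed genes and all 9 had the lower share. The platelet, T cell and granulocyte precursor lists had 0 of 9 expressed genes each (adjusted p = 0.023 by Fisher's exact test), the dendritic and erythroid lists 0 of 8 each (0.029), the natural killer list 0 of 7 (0.049), the interferon list 1 of 14 (0.023) and the Alzheimer list 4 of 22 (ABCA7, ADAM10, PLCG2 and TMEM106B; 0.029). Most calls ended with stricter peak sets by Fisher's exact test: 1 list, the interferon list, was called with a 50% reciprocal overlap, 0 with the top 50% of peaks and 1, the monocyte list, with equal numbers of top peaks. At an unadjusted p under 0.05 by the same test these settings gave 10, 3 and 11 lists, against 11 for the peaks as reported. The natural killer and Alzheimer calls ended without ATAC library 1 (7 lists called), the interferon call without ATAC library 2 (11 called) and the natural killer call without RNA library 3 (8 called), while the microglia, B cell and mast cell lists were called without ATAC library 2 and the mast cell list without RNA library 1 (10 called). Against a background matched on mean expression the dendritic (adjusted permutation p = 0.067) and natural killer (0.057) calls ended and 7 lists were called. With a promoter peak of any library, a setting chosen after seeing the data, the interferon list had 9 of 14 (adjusted p = 0.91 by Fisher's exact test) and the Alzheimer list 11 of 22 (0.11), so both calls ended. The Alzheimer call also ended with promoters of 500 bp and of 2500 bp to each side, and the natural killer call with 500 bp.

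Lists without such a gap included the transcription factor genes, 10 of 18, the cell cycle genes, 8 of 13, lipid and cholesterol genes, 9 of 13, lysosome genes, 7 of 15, autism risk genes, 8 of 16, and housekeeping genes, 5 of 10 (adjusted p at least 0.28 by Fisher's exact test). The homeostatic microglia list had 2 of 12 (adjusted p = 0.10 by Fisher's exact test). Shared promoter peaks were found at EGR1, KLF2, KLF4, JUNB, DUSP1, CD74, PSAP and CD68. Of the MEF2 genes MEF2D had one, at chromosome 1, 156500703 to 156501010 (hg38).

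No peak lay in the promoter window of the MEF2C transcript listed in the files, on the minus strand of chromosome 5 from 88718241 to 88823927 (hg38). Within 100 kb of the transcript 8 merged regions were found, 3 of them in all 3 libraries. The nearest shared region, 88827070 to 88827579, was centred at -3397 bp from the listed start (negative values are upstream), with 12.5, 16.5 and 19.2 normalized tags in libraries 1 to 3. Another, 88883054 to 88883323, was centred at -59261 bp with 30.1, 23.7 and 27.2, and the last, 88680454 to 88680734, beyond the transcript end with 28.4, 27.8 and 20.8. Inside the transcript 2 regions were called, at 88785066 to 88785269 in libraries 1 and 3 and at 88734417 to 88734617 in library 1. The files do not give exons, and 1 transcript is listed per gene, so other start sites of MEF2C are not covered.

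**Figure D5:**
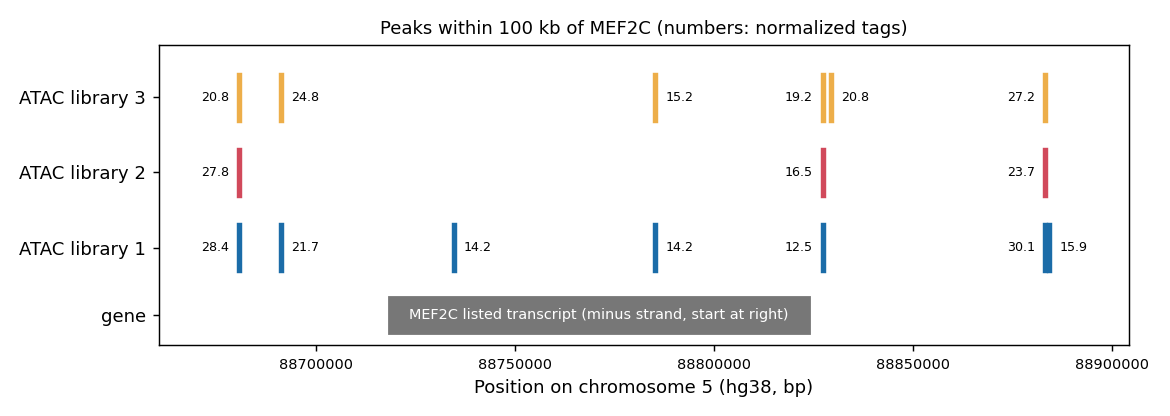
Map of chromosome 5 (horizontal axis, hg38 position in bp) with the listed MEF2C transcript and the peaks of the 3 ATAC libraries, drawn wider than their 200 bp and labelled with normalized tags. The region centred at -3397 bp from the listed start has 12.5, 16.5 and 19.2 normalized tags in libraries 1 to 3.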

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

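The tests in this part were chosen after the result was seen, except the thinning of reads, the set of 8 further neutrophil genes, the wider promoters and the search along the whole transcript, whose bounds were set before those values were computed.

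In 3 of 213 values tested over the 4 RNA libraries, 1 library lay far from the others, where chance gives about 1 in 20, or 10.7, if the libraries are exchangeable. They fall into the pairs 1 and 4, and 2 and 3, which keeps this gap small, so 10.7 is no reference for these data. For MPO the gap was 0.90 of the range, with 67.3 TPM in library 3 against 77.3 to 78.5. The neuronal genes SYT1 (0.86, 0.27 TPM in library 3) and GAD1 (0.84, 0.30 TPM in library 4) lay near the floor.

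RNA libraries 1 and 4, and libraries 2 and 3, resembled each other more than the other pairs. A difference in depth was argued against: after thinning to equal estimated reads the highest r of the other pairs was 0.952 and the lowest r of the close pairs 0.972, with an SD of 0.00025 over 10 thinnings. Dilution by RNA of the erythroid list genes was argued against as the whole cause too. The platelet list was at least 0.90 higher (log2) in libraries 1 and 4 than in libraries 2 and 3. The share of TPM in the erythroid list genes can dilute other genes by only 0.015. Added erythroid cells would also bring transcripts outside the list, which this value leaves out. Added erythroid RNA in general was therefore not settled. Separate donors, cultures or preparation days stay open and untested, since the labels name none, and the design gives no biological explanation to test.

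Transcripts of mature neutrophils were abundant in all 4 RNA libraries, among them CXCR2 at 331 ± 44.2 TPM and MMP25 at 338 ± 108 TPM (SD, n = 4). Reads shared between near-identical copies were argued against as the whole cause, since 6 further neutrophil genes without a known near-identical copy had a median of at least 49.6 TPM in each library. CXCR1 and CXCR2 are themselves listed with 1 copy each. A candidate explanation is RNA of neutrophils among the cells: all 8 further neutrophil genes together also had a median of at least 49.6 TPM in each library, against a bound of 10 set beforehand. None of these 15 genes is in another list, but monocytes may express some of them, and no reference of pure monocytes is analysed here. The labels name no sort.

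Few monocyte list genes had a promoter peak shared by 3 ATAC libraries. The shallow library 2 was argued against as the whole cause, since with a peak of any library 5 of 15 monocyte genes had one against 69.6% of other expressed genes (two-sided Fisher's exact test, p = 0.0041). A start site near the listed one or elsewhere in the listed transcript was argued against as the whole cause. With promoters of 2500 bp to each side 1 of 15 had a shared peak (Fisher p = 0.00031). With a shared region anywhere in the transcript it was 1 of 15 against 53.9% (Fisher p = 0.00026), a share that also depends on transcript length. Both counts asked for peaks in all 3 libraries, and start sites farther upstream were not covered. The tag depth of all 3 libraries together and the sequence content of promoters were not tested and stay open, and no biological explanation was tested. The monocyte call ended with a 50% reciprocal overlap and with the top 50% of peaks, and held with equal numbers of top peaks.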

How the results depend on the processing

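Of the alternative settings, 101 kept the direction and side of the threshold of a tested difference, or left the promoter share within an SD or a count within 1.5 times, 8 moved a value or count further, and none reversed a direction. For the lists with fewer promoter peaks that covers their number only: with a promoter peak of any library 10 were called, of which 3 were not among the 9, with promoters of 2500 bp 10, of which 2 were not, and without ATAC library 2 11, of which 3 were not. The alternatives with RNA libraries 1 and 4 or 2 and 3 alone, and that with a promoter peak of any library, were chosen after seeing the data. With a threshold of 5 TPM, 7795 genes were expressed in place of 12064, by construction. With the top 50% of peaks, shared regions fell to 4884 and their promoter share was 74.5%. The promoter share was 73.9% with promoters of 2500 bp to each side, and 55.8 to 63.2% with 1 ATAC library left out, lowest without library 2. The SD it was judged by, 6.31 percentage points, came from all peaks of each of the 3 libraries, not from shared regions. The 9 lists with fewer promoter peaks became 1 with 50% reciprocal overlap, 0 with the top 50% of peaks and 1 with equal numbers of top peaks (Fisher's exact test; 10, 3 and 11 at an unadjusted p under 0.05, against 11); the cause was not tested. Sign-flip contrasts with 3 libraries cannot go below p = 0.25 (exact test), so they say nothing about stability. With all RNA libraries or with only a pair of them the same test cannot reach 0.05 either. Among the 101 settings, those of the monocyte list contrasts and the MEF2 contrasts therefore kept their side of the threshold by construction. Only the direction of these contrasts could have changed. The motif search and its alternatives were not run, for want of a genome sequence. No paired analysis was possible because the groups are different assays and nothing was tested between them. At most 6255666 tags per ATAC library limit which peaks can be called; the effect of this depth was not tested.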

Other observations

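Immediate-early genes, which cells switch on within minutes of a stimulus or of handling, were not among the lists fixed beforehand and were set together after their values were seen. Their median was 10.0, 8.92, 8.77 and 9.89 on the log2(TPM + 1) scale in RNA libraries 1 to 4, above the monocyte list in libraries 1 and 4. FOS had 3619, 1839, 1761 and 3392 TPM, JUNB 3210, 1740, 1695 and 2714 TPM and IER2 1234, 729.8, 662 and 1086 TPM. FOSB, at 446, 44.8, 39.2 and 438 TPM, is another member. EGR1 and NR4A1 are also in the transcription factor list. The promoters of JUNB, DUSP1, IER2 and EGR1 had a peak in all 3 ATAC libraries, and that of FOSB in none of the 3. Single peaks in the FOS promoter window came from libraries 1 and 3. A merged region with peaks of all 3 libraries also overlapped that window, so FOS had a shared promoter peak by the rule used above.

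The shared ATAC regions with the most normalized tags had 33645, 33514 and 39292 at chromosome 1, 633929 to 634129, and 24667, 25315 and 29092 at chromosome 1, 629838 to 630038 (hg38), against a median of 21.7, 25.8 and 20.8 over all peaks of libraries 1 to 3. The region at chromosome 17, 22521294 to 22521494, had 12326, 13286 and 14384 normalized tags, and that at chromosome 5, 134926958 to 134927158, within the listed PCBD2 transcript, 4503, 4218 and 5129.7. Whether these tags come from sequences with near-identical copies elsewhere, such as mitochondrial DNA, was not tested, because no genome sequence is used, so they are not read as open chromatin.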
